A study of Mus musculus with 4 samples.

How the data were processed

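Transcripts were measured in lineage-negative bone marrow, the cells that remain after magnetic depletion of cells carrying surface markers of mature blood lineages. Per the labels' protocols, marrow of femur and tibia from 4 female mice aged 8 to 12 weeks was pooled for RNA, the lineage-positive cells were depleted on magnetic columns, and labelled cRNA carrying digoxigenin was hybridised to single-colour Applied Biosystems arrays. The series text states that the 4 mice of a pool were matched for age and sex and that the replicate number of an array is its array lot. The wild-type mice were C57BL/6 and the Mtg16-null mice came from a backcross into C57BL/6, per the labels. There were 2 arrays labelled wild type and 2 labelled Mtg16-null, 1 of each genotype in each of 2 array lots. The labels do not say whether the 2 replicates of a genotype came from separate pools of mice. The p-values of single genes therefore measure only the spread between these 4 samples, which may be technical.

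The deposited values are probe intensity on a linear scale, between 28.2 and 3093950 signal units, for 33012 probes on each array. The values show that the authors had already quantile normalized them over the 4 arrays. Sorted values of the 4 arrays differed by at most 11.1 signal units, or 0.286% of the value, and all 4 medians were 470 signal units. The scanner software, background correction, detection calls and any filter are not given in the sources used here, and detection calls were not used here. Read depth does not apply to arrays, and the number of arrays limits the precision.

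Probes were named from the platform annotation supplied with the values. Of the 33012 probes, 14411 had 1 gene symbol, 247 had several and 18354 had none, and only probes with 1 symbol were used for genes. Entrez identifiers of 14402 of these probes were found in the RefSeq gene table of the mouse assembly GRCm38.p6, and the match changed 0 symbols. No genome build is named in the files, so that table served only for names and for the order of neighbouring genes.

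Signals under the 1st percentile of all values, 75.8 signal units, were raised to it before log2 was taken. The brighter 50% of probes by mean log2 signal over the 4 arrays were kept, which left 16506 probes. Where a gene had several kept probes, that with the highest mean was used, giving 8445 genes. Differences are null minus wild type, and were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a variance trend or a robust prior) on all 4 arrays with genotype as the only term. Adjusted p-values are Benjamini-Hochberg values over the 8445 genes unless they are given as adjusted over the list alone, and the threshold was 0.05. A standard error is that of the moderated fit, with 2 residual and 2.11 prior degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

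There were 27 gene lists of cell types, pathways and genes beside the targeted gene, with 517 different genes, of which 406 had a probe with 1 symbol and 326 were kept. They comprise stem and multipotent cell, erythroid, megakaryocyte, early granulocyte, late neutrophil, monocyte and macrophage, dendritic cell, major histocompatibility complex (MHC) class II, early lymphoid, B lineage, T and natural killer cell, mast cell with basophil and eosinophil, plasma cell, stroma with endothelium, S phase, G2 and M phase, cell cycle regulator, Notch target, E protein with Id and Scl factor, adhesion and mobilization, ETO family with partners, interferon response, glycolysis, immediate early, p53 target, neighbour of Cbfa2t3 and Y-linked genes. Each list was compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, and adjusted over the 26 lists with members kept. With the preset correlation, a camera p-value measures spread over genes, not over arrays or mice, so a small one does not show repeatability between mice. The Y-linked list could not be tested, since none of its 3 genes with a probe was in the kept 50%. Uty, Kdm5d and Eif2s3y read between 94.5 and 310 signal units and lay at percentiles 31.2, 22.0 and 6.12 of mean level on these arrays of female mice. Camera was also run with the correlation estimated per list, and fry was run as a test of whether a list's genes move on balance one way.

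Genes were named by a rule of size and repeatability. It took Cbfa2t3, the 15 highest and 15 lowest kept genes by the smaller of their 2 within-lot log2 differences where both lots had the same sign, and up to 2 members per direction of each list that passed camera. Predicted genes without a usual name were skipped. Of other lists the rule took members past the gene test, of which there were 0 with limma at an adjusted p under 0.05. Further list members given below were chosen after their values were seen, as examples of lists that had been fixed. The design, the tests, the lists, the naming rule and most other settings were chosen before the data were examined.

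The replicate number pairs the arrays, because the series text makes it the array lot. Deviations from the group means, across genes, correlated between the 2 arrays of a lot with a Pearson r of 0.503. The fit with the lot as a block was also run. Other settings were quantile or median scaling, no filter or the brightest 25% of probes, a pseudocount of 136 signal units in place of the floor, a variance trend, a robust prior, probes of a gene averaged, a looser threshold of 0.1, and each array left out in turn. Cyclic loess scaling and the lot block together with a variance trend were added after seeing the data.

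The gene test was tested on simulated data for the 8445 genes of the null against wild-type comparison. It called 0 of 50 genes changed 2-fold, 26 of 50 changed 4-fold, 39 of 50 changed 8-fold and 48 of 50 changed 32-fold, with 8 calls among 8232 unchanged genes. With the lot block it called 0, 0, 1 and 41 of 50 at the same folds, and 5 unchanged genes. The simulated arrays held no difference between lots, so the block could only cost degrees of freedom there. The simulation does not show how the block performs on the real arrays. For the same comparison, a simulated list of 13 genes lowered by 1 log2 unit had an adjusted p of 1.4e-11 with the preset correlation, 0.508 with an estimated correlation and 0.0428 with fry. Among 25 unchanged lists, 0 were called by each of these tests, in a simulation without correlation between genes.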

Results

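Gene expression was compared between lineage-negative bone marrow of wild-type mice and of mice lacking Mtg16 (symbol Cbfa2t3), a transcriptional corepressor of the ETO family that is expressed in blood progenitors. Lineage-negative marrow is enriched for stem and progenitor cells. There were 2 arrays of each genotype, each from RNA pooled from 4 mice, and each of 2 array lots held 1 array per genotype. Each array gave signals for 33012 probes with a median of 470 signal units, identical on all 4 arrays because the deposited values had been normalized to a common distribution. The question was which transcripts differ in progenitor-rich marrow without Mtg16, in a study concerned with stem cell mobilization and progenitor proliferation.

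The probe for Cbfa2t3 itself was not lower in the arrays labelled Mtg16-null, here called null arrays. Its signal was 90555 ± 13720 units in wild type and 107046 ± 16300 in the null arrays (SD, n = 2), a log2 difference of 0.24 (SE 0.23, limma adjusted p = 0.702). The difference was 0.24 in both array lots, and the transcript lay at percentile 97.1 of mean level. The position of this probe relative to the deleted part of the gene is not known from the files, so its signal checks the labels in neither direction, and every direction given here rests on the labels.

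Late neutrophil genes fell together in the null arrays, while genes of early granulocyte precursors rose. Ltf, which encodes the granule protein lactoferrin, averaged 16798 ± 323 signal units in wild type and 398 ± 59.2 in the null arrays (SD, n = 2), 42.5-fold lower. Retnlg, a resistin-like secreted factor of neutrophils, fell from 105122 ± 6330 to 2845 ± 40.3 units, and the granule protein genes Ngp and Camp were 29.2-fold and 21.1-fold lower. Elane, which encodes neutrophil elastase of the primary granules, went the other way, from 104651 ± 16643 to 490529 ± 66680 units (4.70-fold, adjusted p = 0.00201 adjusted over the list alone). Of the 13 tested late neutrophil genes, 11 were lower by at least 2-fold in both lots, 7 passed the limma test over all genes (Ltf, Retnlg, Ngp, Camp, Cd177, S100a9 and Chil3), and 11 fell and 1 rose when adjusted over the list alone. The other falls by the list-alone test were Lcn2, Mmp8, Mmp9 and S100a8, which encode granule or cytosolic proteins of neutrophils. S100a9 and S100a8, the subunits of calprotectin, differed in size, with log2 differences of -3.41 and -2.11. The exceptions were Ltb4r1, the leukotriene B4 receptor, which rose 2.13-fold (adjusted p = 0.00354 over the list alone), and Padi4, at a log2 difference of 0.15 (adjusted p = 0.639 over the list alone). The list's median log2 difference was -3.41 (camera adjusted p = 4.16e-14; adjusted p = 0.274 with an estimated correlation).

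Of the 10 early granulocyte genes tested, 7 rose when adjusted over the list alone and 0 fell, and 0 passed over all genes with limma. Prtn3 and Ctsg, serine proteases of primary granules, were 3.24-fold higher and higher by 1.89 on the log2 scale. The transcription factor genes Gfi1 and Cebpe, both required for neutrophil maturation, were 3.95-fold and 3.44-fold higher. Ms4a3, a membrane protein gene of granulocyte-monocyte progenitors, was 4.64-fold higher and Hp, haptoglobin, had a log2 difference of 1.35. Mpo, the myeloperoxidase gene, had a log2 difference of 0.40 (adjusted p = 0.313 over the list alone), Csf3r one of 0.05 (adjusted p = 0.849) and Cebpa one of 1.01 (adjusted p = 0.0969, and 0.0403 with the lot as a block). A single array moved these values: Mpo had 0.001 without null array 1 and 0.81 without null array 2, and Cebpa 1.55 without wild-type array 1 and 0.46 without wild-type array 2. The median of the list was 1.74 (camera adjusted p = 1.78e-07; adjusted p = 0.274 with an estimated correlation). The late neutrophil and early granulocyte lists passed camera with the lot as a block as well, and with cyclic loess and each filter. Quantile and median scaling could change almost nothing, since the values were already quantile normalized. Over all settings with the preset correlation, an array left out among them, the late neutrophil median ran from -3.45 to -3.15. The early granulocyte median ran from 1.55 to 1.76.

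**Figure D1:**
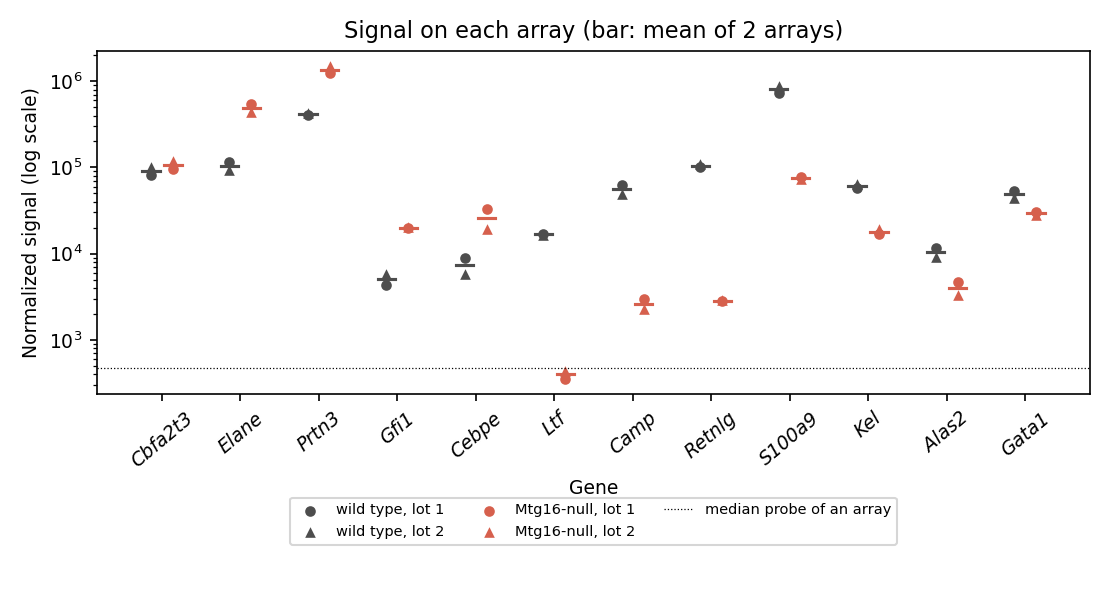
Normalized signal (log scale, signal units) of 12 genes on each of the 4 arrays, with wild type in grey, Mtg16-null in red, lot 1 as circles, lot 2 as triangles and bars for the mean of 2 arrays; the dotted line marks the median probe at 470 units. Ltf lies below that line on both null arrays, and Cbfa2t3 is not lower on the null arrays.

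Over all 8445 genes, 10 passed limma at an adjusted p under 0.05, and all 10 were lower in the null arrays. Besides the 7 late neutrophil genes they were Spon2 (log2 difference -4.84, SE 0.17, adjusted p = 0.0228), a spondin of the extracellular matrix, Trim2 (-4.61, SE 0.21, adjusted p = 0.0351), an E3 ubiquitin ligase, and Oasl1 (-3.13, SE 0.17, adjusted p = 0.0405), an interferon-induced gene. Ltf had a log2 difference of -5.41 (SE 0.20, adjusted p = 0.0228) and Chil3, a chitinase-like lectin, one of -3.15 (SE 0.17, adjusted p = 0.0405). At an unadjusted p under 0.05 there were 1392 genes, 815 higher and 577 lower, against 422 if no gene differed. Over the 16506 kept probes 0 passed (smallest adjusted p = 0.0748), with 2193 at an unadjusted p under 0.05. The number of calls depends on the fit: 0 genes passed with the lot as a block (smallest adjusted p = 0.113, 2054 genes at an unadjusted p under 0.05), 0 without the filter on dim probes (1512 at an unadjusted p under 0.05), 295 with the brightest 25% of probes and 295 with a variance trend. Leaving out wild-type array 1 or 2 or null array 1 or 2 also gave 0 (smallest adjusted p = 0.107, 0.113, 0.148 and 0.0609; 1276, 1438, 680 and 824 genes at an unadjusted p under 0.05), with 3 arrays left and the lone array of its group assumed to vary like the other group.

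By the size rule, the 15 lowest genes were the 10 above with Agtr1a, Lcn2, Lmcd1, Sec14l2 and Tinagl1. Agtr1a, an angiotensin II receptor gene, was 21.1-fold lower (29808 ± 2554 to 1450 ± 463 units, SD, n = 2; adjusted p = 0.0602), and Lmcd1, a LIM domain gene, had a log2 difference of -3.70. Sec14l2, a lipid-binding protein gene, was 9.40-fold lower, and Tinagl1, a matrix protein gene, went from 1331 ± 177 to 160 ± 13 units. The 15 highest were Trap1a, Olr1, Slc6a15, Sh3bgrl2, Sgms2, Elane, Ms4a3, Hivep3, Ppic, Prg2, Afap1l1, Ccm2l, Tslp, Tle6 and Ppp2ca, of which 0 passed limma at an adjusted p under 0.05. Olr1, a scavenger receptor for oxidised lipoprotein, went from 829 ± 169 to 4372 ± 754 units (5.29-fold, adjusted p = 0.0746). Ppp2ca, the catalytic subunit gene of protein phosphatase 2A, went from 5767 ± 744 to 23491 ± 1157 units (4.09-fold, adjusted p = 0.0744), and Tle6, a Groucho family gene, was 4.40-fold higher. Tslp, a cytokine gene, went from 248 ± 53.9 to 1036 ± 125 units. Probes of Y-linked genes, which these female mice lack, read between 94.5 and 310 units on the 4 arrays. The wild-type means of Tslp, Trap1a, Slc6a15, Sh3bgrl2 and Ccm2l and the null means of Tinagl1 and Lmcd1 lay in that range, so the sizes of their differences are not resolved from background. Null array 1 sets the size for Sh3bgrl2, whose log2 difference was 7.00 in lot 1 and 2.23 in lot 2, and 2.09 without that array. The null signals of Ltf and Spon2 (390 ± 12.3 units) were above that range but below the array median.

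Erythroid genes were lower and megakaryocyte genes higher in the null arrays. Kel, which encodes a red cell surface antigen, fell from 61213 ± 4315 to 17991 ± 1685 signal units (SD, n = 2), 3.41-fold. Alas2, the erythroid enzyme that starts haem synthesis, was 2.64-fold lower, and Gata1, the erythroid transcription factor gene, 1.68-fold lower. Ppbp, the platelet basic protein gene, went from 152150 ± 991 to 383510 ± 32204 units, 2.52-fold higher. Of 23 erythroid genes tested, 19 fell and 1 rose when adjusted over the list alone, and 0 passed over all genes. Ermap and Rhd, further red cell membrane genes, both had log2 differences of -1.73. The gene that rose was Nfe2 (0.52), a transcription factor gene that acts in megakaryocytes too. Gfi1b, Hba-a1 and Klf1 did not pass, with log2 differences of -1.17, -0.56 and -0.34. Gfi1b and Hba-a1 passed with the lot as a block (limma adjusted p = 0.0128 and 0.0252 over the list alone). Tfrc, among the 19 that fell, passed only without the block (adjusted p = 0.0486, and 0.0678 with it). The Gfi1b difference was -0.64 without wild-type array 1 and -0.77 without null array 2. For Car1, carbonic anhydrase, the 2 kept probes gave -1.06 and -2.16, the first of them -0.67 without wild-type array 1. The erythroid median was -0.96 (camera adjusted p = 4.42e-12; adjusted p = 0.274 with an estimated correlation). Of 11 megakaryocyte genes, 7 rose and 1 fell when adjusted over the list alone. Those that rose include F2rl2, a thrombin receptor gene (log2 difference 1.24), Rab27b (1.23, and 0.76 without wild-type array 1) and the transcription factor gene Fli1 (0.98), and the one that fell was Vwf, von Willebrand factor (-0.88). Pf4, a platelet chemokine gene, had a difference of 0.52 and did not pass (adjusted p = 0.0533 over the list alone, and 0.0320 with the lot as a block). The megakaryocyte median was 0.77 (camera adjusted p = 3.50e-05; adjusted p = 0.274 with an estimated correlation). Fry with the lot block did not call either list (adjusted p = 0.123 for erythroid and 0.127 for megakaryocyte genes), while camera with the preset correlation called both under each setting tried.

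**Figure D2:**
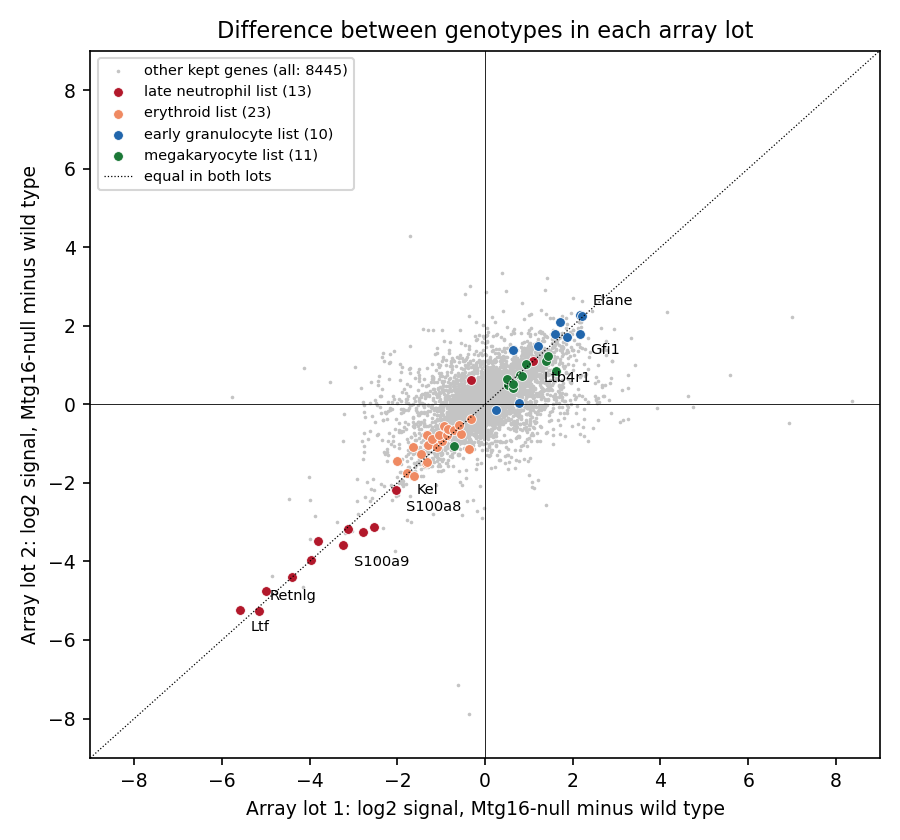
Log2 difference in signal, null minus wild type, of the 8445 kept genes in array lot 1 (x axis) and array lot 2 (y axis), with the late neutrophil (13), erythroid (23), early granulocyte (10) and megakaryocyte (11) lists in colour and a dotted line where both lots are equal. Of the late neutrophil genes 11 lie below -1 in both lots, and Ltb4r1 lies at 1.09 in both.

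Several genes that mark stem and multipotent cells were higher in the null arrays. Slamf1, the CD150 receptor gene used to isolate stem cells, rose from 499 ± 32.7 to 1917 ± 234 signal units (SD, n = 2), 3.83-fold, and Cd34, a progenitor surface antigen gene, rose 2.79-fold. Tek, the angiopoietin receptor gene, rose from 224 ± 55.4 to 852 ± 162 units, and its wild-type level lay within the 94.5 to 310 units read by Y-linked probes, so its fold is not resolved from background. Of 19 genes tested, 6 rose (Slamf1, Tek, Cd34, Esam, Hoxb4 and Hoxa5) and 1 fell (Mllt3, log2 difference -0.74) when adjusted over the list alone. Over all genes 0 of them passed limma, and by sign alone 13 of the 19 were higher and 6 lower. Tek, Cd34 and Esam are also endothelial genes. Kit, the stem cell factor receptor gene, had a difference of -0.19 (adjusted p = 0.538 over the list alone; -0.34 to -0.04 with an array left out) and Msi2 one of -0.50 (adjusted p = 0.0977). The median was 0.51 (camera adjusted p = 0.00593; adjusted p = 0.296 with an estimated correlation). With the brightest 25% of probes, which kept 9 of the genes, the median was 0.31 and the adjusted p 0.287, and over all settings with the preset correlation it lay between 0.00278 and 0.287.

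Lymphoid precursor genes were higher as well. Dntt, the terminal transferase gene, rose from 6292 ± 188 to 18770 ± 3635 signal units (SD, n = 2), 2.96-fold, and Vpreb1, a surrogate light chain gene of early B cells, rose 3.06-fold. Of 5 early lymphoid genes, Dntt, Rag1 (log2 difference 1.06), a subunit gene of the recombinase of antigen receptor genes, and Satb1 (0.63) rose when adjusted over the list alone. Of 9 B lineage genes, Vpreb1, Ebf1 (1.37), a transcription factor gene of the lineage, and Vpreb3 (1.20) rose by the same adjustment. Ly6d had a difference of -0.85 (-0.51 without wild-type array 1) and Cd79b one of 0.77 (0.43 without wild-type array 2). Both had a limma adjusted p of 0.108 over the list alone, and passed with the lot as a block (0.0245 and 0.0448). The early lymphoid median was 0.63 (camera adjusted p = 0.0204; adjusted p = 0.451 with an estimated correlation) and the B lineage median 0.47 (camera adjusted p = 0.00355; adjusted p = 0.274 with an estimated correlation). The early lymphoid call ended without wild-type array 1 (adjusted p = 0.137) or null array 1 (0.0644), and lay between 0.00302 and 0.137 over the settings with the preset correlation. The B lineage call ended without the filter on dim probes (adjusted p = 0.491), with a range of 0.00309 to 0.491 over the same settings. The B lineage median was 0.83 without wild-type array 1, and the early lymphoid median 1.06 with the brightest 25% of probes.

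Genes of MHC class II antigen presentation were higher as a list, with H2-Aa 2.35-fold higher. It was the 1 of 7 members that rose when adjusted over the list alone, against 4 with the lot as a block. Cd74, the invariant chain gene (log2 difference 0.81, adjusted p = 0.109, and 0.0295 with the block), and H2-Oa (-0.28, and -0.15 without null array 2; adjusted p = 0.244) did not pass. The median was 0.75 (camera adjusted p = 0.0187; adjusted p = 0.483 with an estimated correlation). Among monocyte and macrophage genes, F13a1, coagulation factor XIII, was 2.43-fold higher, and Irf8, a transcription factor gene of monocyte and dendritic cell precursors, 1.98-fold higher. With Ccr2 (log2 difference 0.96), 3 of 14 passed when adjusted over the list alone and 0 fell, but with the lot as a block 0 passed by that adjustment (adjusted p = 0.0665, 0.0665 and 0.0729), and the scavenger receptor gene Cd163 had a difference of -0.74 (adjusted p = 0.0576). The monocyte median was 0.19 (camera adjusted p = 0.0445; adjusted p = 0.451 with an estimated correlation). The MHC class II call ended without wild-type array 2 (adjusted p = 0.0981) or null array 1 (0.0644), in a range of 0.0111 to 0.0981 with the preset correlation, and the median was 0.44 without wild-type array 2. The monocyte call ended with the lot as a block (adjusted p = 0.0570), with the brightest 25% of probes (0.0725) and without wild-type array 2 (0.251), null array 1 (0.0796) or null array 2 (0.10), in a range of 0.0180 to 0.251 over the same settings. Its median was 0.35 without wild-type array 1, 0.10 without wild-type array 2 and 0.37 with the brightest 25% of probes.

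Interferon response genes were lower in the null arrays, led by Oasl1, which fell from 5702 ± 168 to 654 ± 38.4 signal units (SD, n = 2), 8.73-fold. Ifit1, an interferon-induced RNA-binding protein gene, went from 784 ± 105 to 237 ± 75.4 units, a null level within the range of the Y-linked probes, with log2 differences of -2.22 and -1.29 in the 2 lots. Of 13 genes tested, 5 fell (Oasl1, Ifit1, Irf7, Usp18 and Isg15) and 0 rose when adjusted over the list alone. With the lot as a block 7 fell and 1 rose by that adjustment. The block added Irgm1 (-0.65, limma adjusted p = 0.0490) and Oasl2 (-0.64, 0.0427) as lower. It added Ifi47 (0.52, adjusted p = 0.0729, and 0.0490 with the block) as higher. Irf7, a transcription factor gene of the response, and Isg15, a ubiquitin-like modifier gene, had differences of -1.57 and -0.99. The median was -0.65 (camera adjusted p = 4.78e-05; adjusted p = 0.274 with an estimated correlation). The brightest 25% of probes kept 4 of the 13 genes and gave no call (adjusted p = 0.240), and neither did fry with the lot block (0.123).

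Genes of DNA replication were lower as a list. Of the 18 tested, 16 were lower, all by less than 2-fold, and 2 were higher. Cdc6, a replication licensing gene, and Ccne1, the cyclin E1 gene, had log2 differences of -0.93 and -0.81, and Cdca7 one of 0.18. Of 18 S phase genes 0 passed limma adjusted over the list alone. Their median was -0.30 (camera adjusted p = 0.00436; adjusted p = 0.274 with an estimated correlation), and without wild-type array 1 the call ended (adjusted p = 0.0667, the upper end of a range from 0.00324 with the preset correlation). Genes of G2 and M phase did not pass, with a median of -0.11 over 25 genes (camera adjusted p = 0.230; median -0.04 without wild-type array 1 and -0.19 without wild-type array 2). Genes of adhesion and mobilization, which act in holding cells in the marrow niche or in their release, were higher as a list of 13. The median was 0.50 (camera adjusted p = 0.0217, and 0.480 with an estimated correlation). Cxcr4, the receptor gene for the niche chemokine, and Selplg, a selectin ligand gene, had log2 differences of 1.22 and 1.13, and 0 genes of the list rose when adjusted over the list alone, against these 2 with the lot as a block (adjusted p = 0.0392 for both). Mmp9, a matrix metalloproteinase gene also in the neutrophil list, fell by that adjustment, with a signal on null array 2 (276 units) within the range of the Y-linked probes, so that the size is not resolved from background. The adhesion call ended without the filter (adjusted p = 0.0566) and without wild-type array 2 (0.146), null array 1 (0.0511) or null array 2 (0.10), in a range of 0.00508 to 0.146 with the preset correlation. The median was 0.29 without wild-type array 2 and 0.31 without null array 2.

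The 26 tested genes beside Cbfa2t3 on its chromosome were lower as a list. Galns, a lysosomal sulfatase gene, and Zfpm1, a partner of Gata1 that is also in the erythroid list, had log2 differences of -1.06 and -0.83, and Irf8 and Mvd had differences of 0.99 and 0.63, the latter 0.38 without wild-type array 2 and 0.40 without null array 1. Of the list 0 passed limma adjusted over the list alone. The median was -0.22 (camera adjusted p = 0.0312; adjusted p = 0.505 with an estimated correlation). The call ended without the filter (adjusted p = 0.105) and without wild-type array 1 (0.117), wild-type array 2 (0.0751) or null array 2 (0.369), in a range of 0.0225 to 0.369 with the preset correlation.

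In all, 13 of 26 lists passed camera with the preset correlation, 8 higher and 5 lower. With the lot as a block 12 passed, and with an estimated correlation 0 passed (smallest adjusted p = 0.274). Estimated correlations of the megakaryocyte, B lineage, S phase and interferon lists were -0.014, -0.079, -0.032 and -0.049. All are below the preset 0.01, so higher gene correlation did not end these calls. Those of the other called lists were above 0.01. That setting also missed the simulated lowered list, without gene correlation (adjusted p = 0.508). Its lack of calls cannot decide whether a list differs. The simulation cannot say which setting is right for correlated genes. Fry called 7 lists, and 2 with the lot block, the late neutrophil (adjusted p = 0.0371) and early granulocyte (0.0101) lists.

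**Figure D3:**
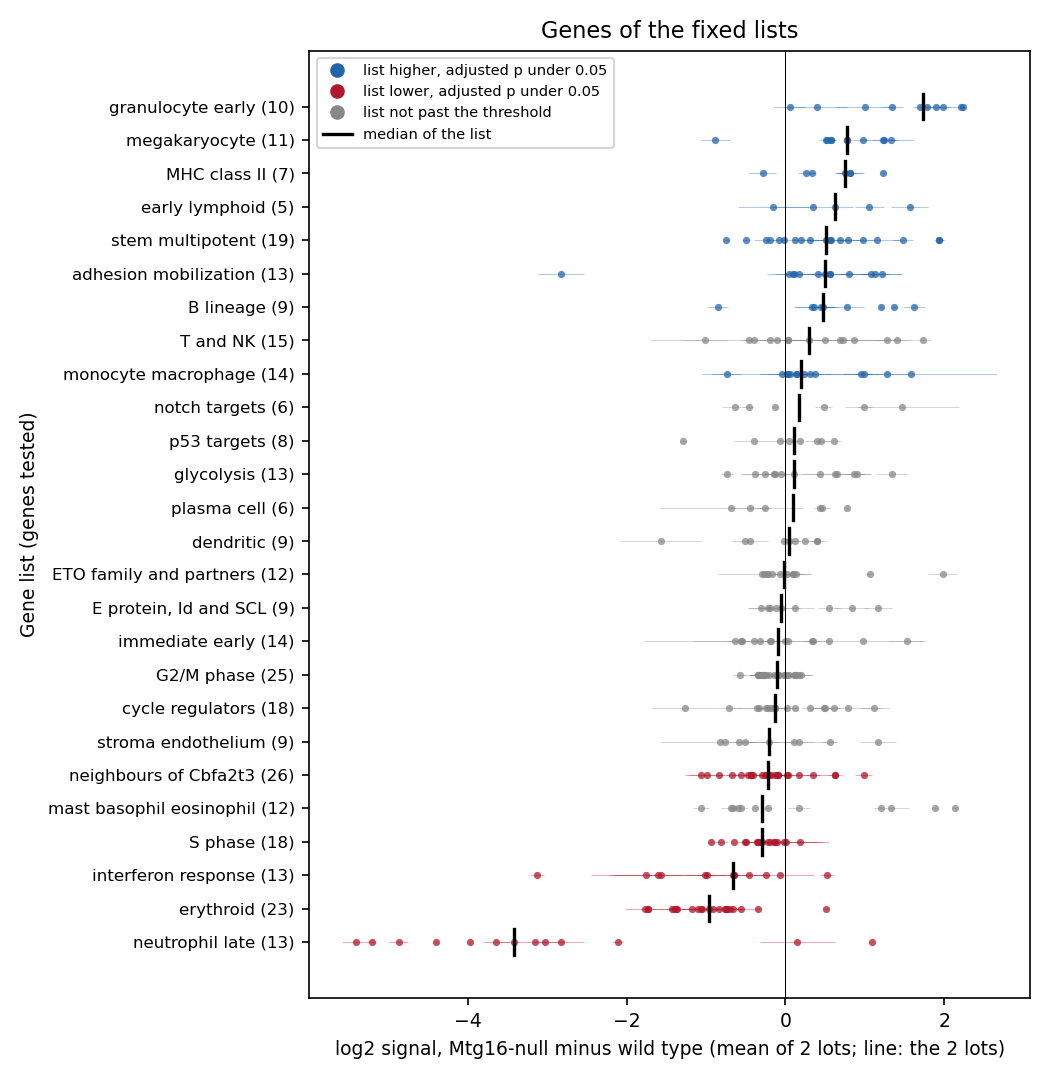
Log2 difference in signal, null minus wild type, of each tested gene of the 26 lists (points, mean of 2 lots, with a thin line between the 2 lots) and the median of each list (black bar), in blue for lists that camera called higher, red for lower and grey for neither. The medians run from -3.41 for the late neutrophil list to 1.74 for the early granulocyte list.

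Lists of other cell types did not pass as a whole, though single members did when adjusted over their list alone. Members of the mixed list of mast cell, basophil and eosinophil genes went both ways. Prg2, the eosinophil major basic protein gene, rose from 100477 ± 10582 to 441733 ± 60772 signal units (SD, n = 2), 4.39-fold, and Epx, eosinophil peroxidase, rose 3.69-fold, while Cpa3, a mast cell carboxypeptidase gene, fell 1.61-fold and Mcpt8, a basophil protease gene, fell 1.57-fold. Of the 12 genes, 4 rose (Prg2, Epx, Prg3 and Hdc, the histamine-forming enzyme gene of mast cells and basophils), 3 fell (Tph1, Cpa3 and Mcpt8) and the others, among them Fcer1a (log2 difference -0.59), did not pass, and camera gave an adjusted p of 0.930, with a median of -0.30 and a mean of 0.22. With the lot as a block 4 rose and 5 fell, Fcer1a among them (adjusted p = 0.0361 over the list alone), and the median was 0.04 without the filter on dim probes and 0.17 with the brightest 25%. Of 15 T and natural killer cell genes, 3 rose (Nkg7, 3.33-fold, Klrb1c and Gzma) and 0 fell, with a median of 0.30 (camera adjusted p = 0.0987). That median was 0.04 over 23 genes without the filter, 0.17 with the brightest 25% of probes, 0.14 without null array 1 and 0.17 without null array 2. Nkg7, a granule membrane protein gene, Klrb1c, a natural killer receptor gene, and Gzma, granzyme A, are genes of cytotoxic cells, as is Gzmb, granzyme B, whose log2 difference was -1.01 (adjusted p = 0.0757 over the list alone). The dendritic cell median was 0.04 (9 genes, mean -0.15, camera adjusted p = 0.920), the plasma cell median 0.09 (6 genes, adjusted p = 0.725; -0.23 without the filter), and the stroma and endothelium median -0.21 (9 genes, adjusted p = 0.610; 0.37 over 2 genes with the brightest 25%). With the lot as a block 1 stroma and endothelium gene rose over the list alone, Kdr, an endothelial growth factor receptor gene (1.16, and 0.58 without wild-type array 1), and 1 fell, Col1a1, a collagen gene (-0.76).

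Among regulators, Hes1, a Notch target gene, rose 1.99-fold when adjusted over its list alone. Id1, an inhibitor of E proteins, was 2.25-fold higher and passed by that adjustment, but not with the lot as a block (adjusted p = 0.0267 and 0.0566). Cbfb, the partner of Runx proteins, rose 2.09-fold by the same adjustment, and with Gfi1 was 1 of 2 such genes among 12 of the ETO family and its partners. Pgam1 and Hk2, enzymes of glycolysis, with log2 differences of 1.35 and 0.90, passed over their list alone but not with the lot as a block (adjusted p = 0.0446 and 0.0521 for both). Sesn2, a p53 target gene, fell (-1.29). None of these lists passed camera: the median was 0.18 for 6 Notch targets (adjusted p = 0.448), -0.06 for 9 E protein, Id and Scl genes (0.610, mean 0.20), -0.02 for the ETO family (0.759, mean 0.18), 0.10 for 13 glycolysis genes (0.292) and 0.11 for 8 p53 targets (0.830, mean -0.01). Cell cycle regulators had a median of -0.13 over 18 genes (adjusted p = 0.991, mean 0.01), with Ccnd2, the cyclin D2 gene, at 1.12, and 0 passed over the list alone. Immediate early genes, which respond to cell handling, had a median of -0.09 over 14 genes (adjusted p = 0.895, mean 0.07). Each of these 7 medians moved by over 1.5 times in some setting. The Notch median was 0.50 without wild-type array 1, 0.37 without null array 2 and 0.02 without the filter on dim probes. The glycolysis median was 0.43 without wild-type array 1, 0.16 without wild-type array 2, 0.42 without null array 2, 0.43 with the brightest 25% of probes and 0.27 without the filter.

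The differences between genotypes were compared between the 2 array lots, whose pairs share no array. Whether the pairs share RNA is not known, since the labels do not say if replicates came from separate pools. Agreement between lots may therefore be technical. The 11 late neutrophil genes that fell were lower in both lots, with -5.16 and -5.25 for Retnlg and -2.79 and -3.26 for Mmp8. These 11 were called on the same arrays, which largely sets that outcome in advance. Padi4 had -0.32 and 0.62. Elane had 2.21 and 2.26. In both lots, 40 genes were lower and 12 higher by at least 4-fold, with 0 in opposite directions, and 15 were lower and 0 higher by at least 8-fold. At 2-fold or more, 185 were lower in both lots, 275 higher in both and 24 in opposite directions. Across the 8445 genes, which are not independent replicates, the differences correlated with a Pearson r of 0.550 and a Spearman rho of 0.545, and 5949 genes (70.4%) had the same sign. A lot holds 1 array per genotype, so no test within a lot was possible. Between lots, with genotype in the fit, limma found 0 genes (smallest adjusted p = 0.104), with 1534 at an unadjusted p under 0.05. The SD over genes was 0.58 for the lot difference and 0.62 for the genotype difference on the log2 scale. With the brightest 25% of probes 518 genes differed between lots and the correlation of genotype differences was 0.817. Arrays of lot 2 correlated at 0.968 across kept probes, above the 0.949 between wild-type arrays and the 0.959 between null arrays, and arrays of lot 1 at 0.952.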

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

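Cyclic loess and the lot block with a variance trend were chosen after seeing the data. The number of genes called by limma, 10, stayed at 10 with a robust prior or averaged probes, and was 11 with cyclic loess and 14 with the pseudocount. It was also 10 with quantile or median scaling, which could change almost nothing, since the deposited values were already quantile normalized. It fell to 0 with the replicate block (smallest adjusted p = 0.113, 2054 genes at an unadjusted p under 0.05), to 0 without the filter (0.101, 1512 genes) and to 0 with any 1 of the 4 arrays left out (lowest 0, highest 0; adjusted p from 0.0609 to 0.148, 680 to 1438 genes at an unadjusted p under 0.05). It rose to 295 with the brightest 25% of probes (192 higher, 103 lower, with all 5 of the 10 genes that this filter keeps), 295 with a variance trend (181 higher, 114 lower, all 10 among them), 1771 with the replicate block and a variance trend together (963 higher, 808 lower, all 10 among them) and 182 at an adjusted p under 0.1 (104 higher, 78 lower). The cause of these changes in number was not tested. The brightest 25% of probes left out dim probes and also left fewer genes to test (4967). Over kept probes, of which 0 passed, the count was 331 with the brightest 25%, 4 with the pseudocount, 234 with a variance trend, 2689 with the replicate block and a variance trend, 14 at an adjusted p under 0.1, and 0 to 1 with an array left out (1 without null array 2). No gene taken by the naming rule changed direction in any of these settings. With an array left out, 82 of the 326 tested list genes did, among them Padi4 (-0.18 without wild-type array 2) and Csf3r (-0.22 without wild-type array 1), but 0 of the 85 that passed limma adjusted over a list alone. The named genes and these 85 were chosen on the same arrays for steady differences, which largely sets this outcome in advance. The difference of 182 of the 326, 3 of them among these 85, turned or moved by over 1.5 times, and with the replicate block 80 of the 87 calls over a list alone, counted once per list, stayed, 7 were lost and 22 were gained. The Cbfa2t3 difference stayed between 0.09 and 0.40 and was not called in any setting run for it.

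Of the 13 lists called by camera, 0 passed with an estimated correlation, 7 with fry and 2 with fry and the replicate block. With an estimated correlation the adjusted p was 0.274 for the erythroid (median -0.96), megakaryocyte (0.77), early granulocyte (1.74), late neutrophil (-3.41) and interferon (-0.65) lists. That setting also missed the simulated shift (0.508), without gene correlation. With fry and the replicate block the adjusted p was 0.123 for the erythroid (-0.96), 0.127 for the megakaryocyte (0.77) and 0.123 for the interferon (-0.65) list. With the brightest 25% of probes the interferon median was -0.45 over 4 genes (adjusted p = 0.240). The replicate block ended the monocyte call and changed no other camera call.

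For lists that camera did not call, the direction of the test, which need not be that of the median, changed in some settings, with the cause not tested. It did so for the mast, basophil and eosinophil list with the replicate block (median -0.297), the dendritic list with the brightest 25% (0.0814), the p53 list with fry, with or without the replicate block (0.113 and 0.113), cell cycle regulators with cyclic loess (-0.134), no filter (-0.128), the brightest 25% (-0.140) and the pseudocount (-0.131), and the stroma list with the brightest 25% (0.366 over 2 genes), and with an array left out for these lists but the dendritic one and for plasma cell and immediate early genes. Some medians turned sign in other settings: the mast, basophil and eosinophil median was 0.0386 without the filter and 0.168 with the brightest 25%, the ETO family median 0.0235 and 0.0597 in these settings, the plasma cell median -0.227 without the filter, and that of immediate early genes 0.188 with the brightest 25%. With an array left out, medians ran from -0.333 to -0.0252 for the mast, basophil and eosinophil list, 0.0202 to 0.202 for p53 targets, -0.0998 to 0.0605 for cell cycle regulators, -0.462 to 6.199e-04 for stroma, 0.0104 to 0.356 for plasma cell and -0.114 to 0.166 for immediate early genes, -0.0918 to 0.118 for dendritic cell, -0.114 to 0.116 for E protein and -0.158 to 0.0496 for ETO family genes.

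Agreement between lots moved from 70.4% of genes with the same sign (Pearson r 0.550) to 63.5% (0.307) without the filter and 75.3% (0.817) with the brightest 25%. Genes differing between lots went from 0 to 518 with the brightest 25%. Leaving out an array was not run for the lot comparison, which leaves no residual degrees of freedom on 3 arrays. Signal over background limits the dim genes, and no detection call was used here.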

Other observations

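All tests in this part were chosen after the result was seen, except the percentile of the run of genes beside Cbfa2t3 among all runs and among runs of like span. Genes whose symbol begins with Clec, which share a C-type lectin domain but not a function, were higher in the null arrays as a set. Of the 14 tested, 12 were higher in both lots and 0 lower in both, but 0 passed limma at an adjusted p under 0.05 (7 at an unadjusted p under 0.05). Clec2i had a log2 difference of -0.35 and Clec9a one of -0.01. Clec5a, Clec4e, Clec4d and Clec12a, receptors of myeloid cells, had log2 differences of 1.81, 1.76, 1.55 and 1.48 (limma adjusted p = 0.101, 0.0744, 0.0850 and 0.0840). The median of the set was 0.67 (camera adjusted p = 0.00112 over 122 symbol families; adjusted p = 0.969 with an estimated correlation) and 0.66 after cyclic loess, and the next such family, Fkbp, had an adjusted p of 0.123. Of 7666 kept probes with no gene symbol, 11 were higher and 27 lower by at least 4-fold in both lots, and 0 were higher and 8 lower by at least 8-fold.

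Late neutrophil genes were lower and early granulocyte genes higher in the null arrays, with medians of -3.41 and 1.74. Fewer mature granulocytes alone would enrich the remaining cells alike. The mean of the early granulocyte list (1.46, SD over genes 0.75) lay 2.44 log2 units above that of the erythroid list (-0.98, SD 0.51). The gap was 2.49 and 2.40 in the 2 lots. The megakaryocyte (0.69), early lymphoid (0.69), B lineage (0.64, SD 0.73) and stem and multipotent (0.50) means lay nearer to the early granulocyte mean. The values thus argue against that explanation alone only with the erythroid list as comparison, chosen after the result was seen. Fewer lineage-positive cells of all kinds left after the magnetic depletion would lower T, natural killer and B lineage genes along with late neutrophil genes. The T and natural killer and B lineage means were 0.36 (SD 0.77) and 0.64 (SD 0.73), against -3.14 (SD 1.93) for late neutrophil genes. The medians were 0.30 (0.04 without the filter, 0.14 and 0.17 without null array 1 or 2) and 0.47 (0.83 without wild-type array 1). Both lists rest in part on dim genes, but with the brightest 25% of probes the medians were 0.17 over 4 genes and 0.47 over 7. The 2 lists were thus not lower as a whole, but neither median lay above 0 by more than its SD over genes. T, natural killer and mature B cells may also have been too few in the wild-type samples to show a loss. These values therefore cannot decide whether all such cells were lost equally. An unequal loss cannot be told apart from other explanations, since erythroid genes were lower too (median -0.96). The B lineage values also rest in part on genes of B cell precursors. For the late neutrophil genes a lower carry-over of mature granulocytes cannot be told apart from lower expression, since no table separates them; the members differed unequally (SD 1.93), and the abundant S100a9 and S100a8 went from 808276 and 245371 signal units to 75468 and 56751. The genotype itself stays open as an untested explanation, and counts of granulocyte stages in the depleted marrow, not analysed here, would be needed to separate it from carry-over.

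Genes beside Cbfa2t3 were lower as a group. The 25 measured genes before and 25 after it in RefSeq order had a median of -0.28 (35 of 50 lower in both lots; -0.31 and -0.27 by lot), at percentile 0.0118 of 8442 such runs, which overlap, so that about 165 are separate. The lowest run sharing no gene with it had a median of -0.24, and 24 flanking genes outside the fixed list had -0.29, but the SD of the run was ordinary (percentile 24.3) and Irf8 went the other way (0.99). A dense gene region as such is argued against, as the run lay at percentile 0.106 of 946 runs of like genomic span. These runs overlap too and include the run itself, so fewer are separate and the percentile overstates how rare its median is. A segment of donor-strain chromosome kept around the targeted locus during backcrossing is a candidate explanation, and a regional effect of the targeted allele itself stays open and was not tested.

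The Cbfa2t3 probe was not lower in the null arrays. If the late neutrophil difference follows the genotype, labels exchanged in 1 lot would give that list opposite signs in the 2 lots. Its median was below 0 in both lots, at -3.24 in the lot nearer 0. If the difference comes from carry-over of mature granulocytes, which stays open, these signs do not check the labels. With a probe inside the deleted part, labels exchanged in both lots would give a large rise in the null arrays. Correct labels would give a large fall with such a probe. The log2 difference was 0.24 (SE 0.23), neither a large rise nor a large fall, so it does not check the labels. A probe outside the deleted part stays open, because the files do not place the probe, and such a probe could not show a label error in both lots.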
